A study of Arabidopsis thaliana with 24 samples.

How the data were processed

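RNA of whole Arabidopsis thaliana seedlings was measured in 24 libraries, 3 in each of 8 groups. Per the labels, seedlings of the accessions Columbia (Col) and Landsberg erecta (Ler) and of the 2 reciprocal F1 hybrids between them were grown for 9 days under continuous light at 22 °C after 4 days of stratification. Each background was present as wild type (WT) and as the prmt5-5 mutant, an allele isolated in Col and moved into Ler by 7 generations of backcrossing. Per the labels' protocols, polyadenylated RNA from 3 µg of total RNA was made into libraries and sequenced as reads of 100 bp. Per the submitters' processing notes, reads were trimmed with Trim Galore, inspected with FastQC and aligned with STAR 2.7.9a to TAIR10. The counting tool, the gene annotation, the use of strand and the rule that assigned an F1 read to an allele are not given in the sources used here.

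The authors deposited raw counts per gene: 1 count per parental library, and for each F1 library 1 count for the Col allele and 1 count for the Ler allele. All values were integers, and no scaling, filter or batch term was found in them. Each table held 33602 genes, of which 3 had no value in the Ler columns. Low allele counts were mostly even, so intervals and floors from counts cover counting error only and are too narrow where both ends of a fragment were counted. Gene identifiers were matched to the RefSeq annotation of TAIR10.1, which gave names and positions to 32835 of them, and 767 had no match. The counts are totals per gene, so splice junctions and splice sites were not analysed here. Genes with a near-identical copy (the MATE transporter pair AT2G04050 and AT2G04070, the light-harvesting and small Rubisco subunit genes, the NLR clusters) and overlapping or antisense genes are uncertain, since reads can be split between copies in a way that is not given in the sources used here.

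Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit, TMM normalisation, filterByExpr) in R 4.3.3, with an adjusted p (Benjamini-Hochberg) under 0.05 as the threshold. All tests were two-sided. The 12 parental libraries were fitted together with 1 mean per group. This fit gave the prmt5-5 effect in Col and in Ler, the accession by genotype interaction (the effect in Ler minus the effect in Col), and the difference of Ler from Col in WT and in prmt5-5. The allele counts of each of the 12 F1 libraries were summed per gene and fitted in the same way, which gave the prmt5-5 effect in F1 Col x Ler and in F1 Ler x Col. F1 groups carry the parents in the order of the labels, and which accession was the seed parent was not read from the order. The test of the difference between these 2 F1 effects was added after the data were seen.

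For allelic tests, the 24 allele columns of the F1 libraries were fitted with library as a block and a Ler against Col allele effect for each group, and both alleles of a library had the same normalisation factor. The means of the allele effect over both crosses were tested in WT and in prmt5-5, as were their difference between genotypes (the change of the allelic ratio) and their difference between crosses. A further fit of the 6 WT parental and 6 WT F1 libraries tested the parental difference minus the allelic difference. A parental difference that is absent between alleles in the same cells is what action in trans would give, but loss of the reads of one allele or differences between the seedling samples would give it too. Fold changes are given as log2 values with their standard errors (SE), and levels as mean counts scaled to the library total after TMM (CPM) with standard deviations (SD). The Ler share of a gene is the percentage of its allele counts that came from the Ler allele.

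A Col segment kept in the Ler mutant was sought from the Ler shares in gene order. The search took runs of at least 5 genes with 20 or more allele counts per group, a Ler share under 10% in the prmt5-5 F1 of both crosses and of 20% or more in the WT F1 of both crosses, with up to 2 failing genes. Segments present in part of the plants were sought after the data were seen, in bins of 200 kb with at least 10 genes and a Ler share under 40% in prmt5-5 F1.

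The genes named were set by a rule. It took PRMT5, the 8 genes (5 in the F1 genotype, interaction and allelic change comparisons) with the largest change in each direction, and the 4 members of each gene list with the smallest p. The largest changes were ranked among genes past the threshold with a mean count of at least 10 in both groups and no overlap between replicates, or, for allelic tests, the same sign in every library. Genes in the Col segments were marked or named apart in the comparisons of Ler and F1, but they stayed in the list counts and list tests. The text gives part of these genes. Genes that only the Ler against Col comparison in prmt5-5 or the parental minus allelic comparison names, and genes traced from one comparison to another, were chosen after their values were seen.

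There were 22 gene lists with 401 distinct genes: PRMT family, circadian clock, floral repressors, floral promoters and autonomous pathway, Sm, LSm and U1 snRNP, U2, U5 and NTC splicing factors, SR proteins and hnRNP, cold, drought and ABA response, salicylic acid and camalexin defence, jasmonate response, photosynthesis, cell cycle, type-A response regulators, auxin response, aliphatic glucosinolates and myrosinases, heat shock, flavonoids and anthocyanins, NLR immune receptors, genes linked to PRMT5 in earlier work, root and root hair, seed storage and late embryo, and floral organ identity. Members past the threshold were counted over all genes tested and adjusted over the list alone. Lists were tested against the other genes with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and again with an estimated correlation. List p-values below are adjusted over the lists and come from the preset correlation unless the text says otherwise.

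Similarity of the prmt5-5 effect between backgrounds was described with Pearson's r and Spearman's rho across genes, which are not independent replicates. Shares of counts have exact Clopper-Pearson intervals (95%) over the summed counts, and a count of 0 was given the floor of 3 counts. The other tests of counts, the list test and the search for runs of genes were tried on simulated data with changes of known size. The difference between the F1 effects, the organelle test and the search in bins were not. Part of the shares recovered is given with the limits of the results. Alternatives were DESeq2 1.42.0, RLE factors, other filters, a 2-fold threshold, fits on the compared groups alone, the replicate number as a block, each cross alone, genes outside the Col segments, and each library left out in turn. The groups, comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. No library was left out. Single results for some genes are not reported here, and these genes stayed in the counts of lists and alternatives.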

Results

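The data were gene-level RNA counts of whole Arabidopsis seedlings from 24 libraries in 8 groups of 3. PRMT5 is a protein arginine methyltransferase that places symmetric dimethylation on histones and on Sm proteins of the spliceosome. Wild-type (WT) and prmt5-5 seedlings were compared in the accessions Col and Ler and in both reciprocal F1 hybrids. The parental libraries held between 36993754 and 72714639 counts. The F1 libraries held between 6047673 and 29376326 counts that could be assigned to an allele. The labels do not say whether replicates were separate plantings, so p-values measure only the spread between these samples.

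PRMT5 (AT4G31120, chromosome 4, 15132011 to 15136696, TAIR10.1) had similar RNA levels in WT and prmt5-5 of each background, so its total RNA did not separate mutant from WT. Its level was 31.5, 29.9 and 32.4 CPM in the 3 Col WT libraries and 36.2, 30.1 and 34.6 CPM in Col prmt5-5. In Ler it was 32.3, 34.7 and 33.1 CPM in WT and 37.2, 32.9 and 29.7 CPM in prmt5-5. The log2 fold change of PRMT5 was 0.10 (SE 0.09, adjusted p = 0.412) in Col, and its adjusted p was 0.983 in Ler. The summed alleles of PRMT5, which hold only counts assigned to an allele and are not comparable with the parental levels, gave 12.1, 14.9 and 14.2 CPM in F1 Col x Ler WT, 15, 14.8 and 12.3 CPM in its prmt5-5 counterpart, 18.9, 10.5 and 12.5 CPM in F1 Ler x Col WT, and 12.1, 14.3 and 15.9 CPM in its prmt5-5 counterpart. The alleles did separate the genotypes. The Ler allele of PRMT5 had 40, 76, 94, 70, 153 and 122 counts in the 6 WT F1 libraries, or 53.1% of 1046 counts (95% interval 50% to 56.1%). In the 6 prmt5-5 F1 libraries it had 0 counts in 5 and 2 counts in the other, or 0.189% of 1057 counts (95% interval 0.0229% to 0.682%). A count of 0 in the prmt5-5 F1 library with the fewest PRMT5 counts, 102, allows a share of up to 2.94%. Per the labels, both parents of these F1 plants were prmt5 mutants, and the allele was isolated in Col. Both PRMT5 copies are therefore derived from Col, and the low Ler share follows from the crosses.

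**Figure D1:**
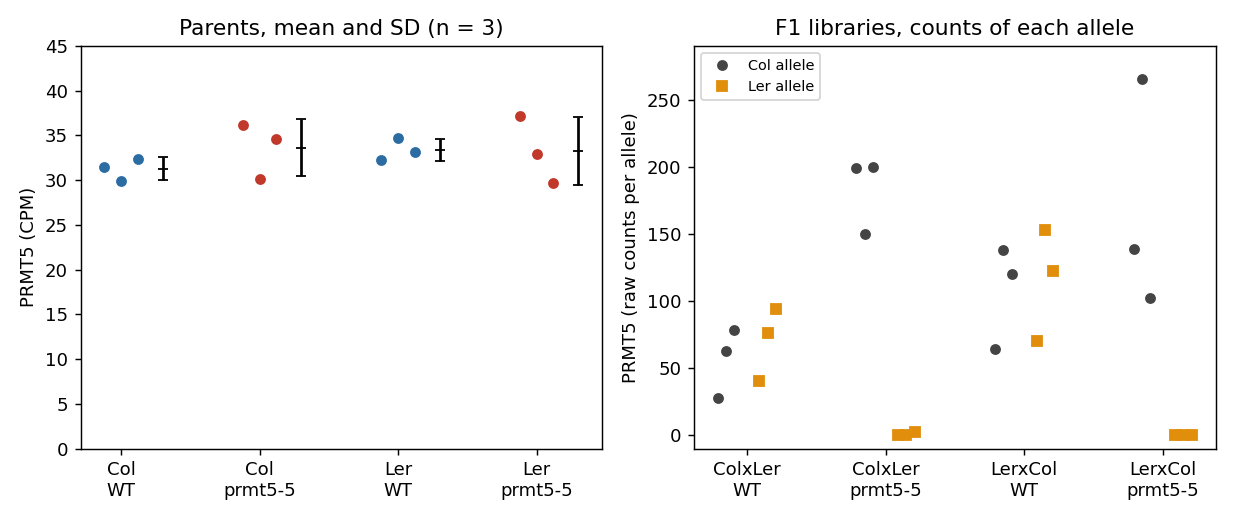
PRMT5 in every library. The left panel plots CPM in the parents (points are libraries, bars the mean and SD, n = 3), and the right panel plots raw counts of each allele in the F1 libraries; Ler allele counts lie between 40 and 153 in WT F1 libraries and between 0 and 2 in prmt5-5 F1 libraries.

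The first comparison asked how the prmt5-5 mutation changes the transcriptome of Col. The MATE efflux transporter AT2G04050 rose from 0.884 to 96 CPM, a log2 fold change of 6.76 (SE 0.37, n = 3 per group, adjusted p = 9.81e-07). The transcription factor gene NAC044 rose by 4.46 on the log2 scale (SE 0.14) and the glucosyltransferase gene UGT74E2 by 3.71 (SE 0.33). The NIMA-related kinase gene NEK2 rose from 44.7 to 140 CPM. The kelch repeat gene AT5G50310 had the lowest log2 fold change of the named genes, with 46.1 CPM (SD 0.675) in WT and 4.01 CPM (SD 0.296) in prmt5-5, and fell by 3.52 on the log2 scale (SE 0.08, adjusted p = 6.55e-12). In each of these genes all 3 prmt5-5 libraries lay beyond all 3 WT libraries. Other genes with large rises were AT5G28335 (6.36), AT2G04070 (4.37), the threonyl-tRNA synthetase family gene AT1G17960 (4.19), the P-loop ATPase gene AT2G18193 (4.10) and AT5G13210 (3.69). Other genes with large falls were LEA4-5 (-2.63), MRU1 (-2.60), the GRAS factor gene AT3G13840 (-2.49) and PCC1 (-2.30). Of 22924 genes tested in Col, 6245 changed, 3397 upward and 2848 downward, and 861 of these changed by at least 2-fold.

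Splicing factor genes tended upward in Col prmt5-5. Of 32 Sm, LSm and U1 snRNP genes, 9 rose, 0 fell and 23 did not pass the test (9 and 0 adjusted over the list alone; list test adjusted p = 0.000449, but adjusted p = 0.653 with an estimated correlation). SmD1a rose by 0.61 (SE 0.12), the snRNP assembly factor gene GEMIN2 by 0.53 (SE 0.08) and LUC7B by 0.53 (SE 0.10). Of 22 SR protein and hnRNP genes, 10 rose and 0 fell (11 and 1 adjusted over the list alone; p = 0.00142, but adjusted p = 0.653 with an estimated correlation), with SR34A at 0.94 (SE 0.10), PTB1 at 0.84 (SE 0.11) and SC35 at 0.49 (SE 0.06). Of 15 U2, U5 and NTC factors, 3 rose and 0 fell (2 and 0 adjusted over the list alone; list test adjusted p = 0.068), among them PRP8B at 1.47 (SE 0.17). Of 10 genes linked to PRMT5 in earlier work, 5 rose and 0 fell (7 and 0 adjusted over the list alone; p = 0.00203, but adjusted p = 0.377 with an estimated correlation), including the RNA-binding floral regulator FLK at 1.07 (SE 0.07) and the cyclin-dependent kinase inhibitor KRP1 at 0.82 (SE 0.12). Of the 9 PRMT family genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with PRMT3 at 0.59.

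Clock and flowering genes changed in both directions in Col. All seedlings were 9 days old and no time course was sampled. A shift in clock timing is therefore not told apart from a change of level, here and in the other comparisons. Of 27 circadian clock genes, 8 rose and 9 fell (10 and 10 adjusted over the list alone), and the list median of 0.11 was positive while the mean of -0.05 and the list test were negative. The morning genes CCA1 and LHY fell, by 1.07 (SE 0.12) and 0.99 (SE 0.13), as did their coactivator gene LNK2 (-1.29), while PRR9 rose by 1.06 (SE 0.13). Of 12 floral repressors, 5 rose and 0 fell (5 and 0 adjusted over the list alone). The floral repressor FLC rose from 0.665 to 1.79 CPM (log2 1.40, SE 0.32, adjusted p = 0.00512), MAF5 rose by 1.71 and SMZ by 0.94. Of 13 floral promoters and autonomous pathway genes, 2 rose and 5 fell (3 and 5 adjusted over the list alone), and the list median of 0.07 differed in sign from the mean of -0.22 and the test. The florigen gene FT fell by 1.22 (SE 0.23) and the floral integrator SOC1 by 0.90 (SE 0.10).

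Photosynthesis genes fell in Col: 0 rose and 17 of 29 fell (0 and 21 adjusted over the list alone; p = 6.23e-07, but adjusted p = 0.653 with an estimated correlation). LHCB3 dropped from 3460 to 1820 CPM and LHCB2-1 from 2210 to 1190 CPM. Among 13 auxin response genes 1 rose and 5 fell (1 and 7 adjusted over the list alone), IAA6 by 1.42. Of 25 aliphatic glucosinolate and myrosinase genes 10 rose and 3 fell (11 and 3 adjusted over the list alone), with CYP79F2 at 0.74. Of 17 flavonoid and anthocyanin genes 4 rose and 0 fell (4 and 0 adjusted over the list alone), including the anthocyanin regulator PAP1 at 1.36 (SE 0.29). Of 28 NLR immune receptor genes 3 rose and 5 fell (3 and 6 adjusted over the list alone), with the downy mildew resistance genes RPP7 at -1.06 (SE 0.08) and RPP4 at 0.58 (SE 0.09). Of 30 cell cycle genes 5 rose and 0 fell (5 and 0 adjusted over the list alone), with CYCB1-1 at 0.62.

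Of the 22 lists, 4 passed the list test in Col with the preset correlation: Sm, LSm and U1 snRNP, SR and hnRNP, photosynthesis, and genes linked to PRMT5 in earlier work. Of 22 cold, drought and ABA genes 4 rose and 6 fell (5 and 6 adjusted over the list alone), and of 18 jasmonate genes 2 rose and 3 fell (4 and 3 adjusted over the list alone), VSP2 by 0.70 downward. Of 25 salicylic acid and camalexin genes 1 rose and 1 fell (1 and 0 adjusted over the list alone), and the median of 0.11 differed in sign from the list test. Of 9 type-A response regulators of cytokinin signalling 0 rose and 1 fell (0 and 1 adjusted over the list alone), and of 10 heat shock genes 0 rose and 1 fell (0 and 1 adjusted over the list alone). Among the organ and stage markers, 1 rose and 1 fell of 21 root and root hair genes (1 and 1 adjusted over the list alone), and 0 passed the test of 4 measured seed storage genes and of 6 floral organ identity genes (0 adjusted over the list alone in both), with list medians of -1.825 and -0.881.

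The same comparison in Ler asked how the mutation acts in the accession into which it was crossed. AT5G28053 rose from 0.241 to 36.2 CPM (log2 7.27, SE 0.21, n = 3 per group, adjusted p = 7.17e-15), although Col had 0.0267 CPM or less in both genotypes. AT4G05370 rose by 6.32 (SE 0.33), AT2G04050 by 5.66 (SE 0.32) and NAC044, which lies in a Col region found on chromosome 3, by 4.52 (SE 0.13). The receptor kinase genes CRK23 (5.10, SE 0.55) and CRK7 (4.87, SE 0.71) and PNP-A (4.75, SE 0.62) also rose. The lipid recognition gene AT2G16005 fell from 115 to 6.93 CPM (log2 -4.04, SE 0.25, adjusted p = 1.24e-06) and the glycine-rich protein gene AT2G05510 from 138 to 14.2 CPM. AT2G04070 (5.73) and AT4G05380 (5.63) rose, and CYP76G1 (-2.77) and LEA7 (-2.76) fell. The defensin gene PDF1-2A fell by 3.29, but without Ler prmt5-5 replicate 2 or replicate 3 its adjusted p was up to 0.056. Of 22924 genes, 8281 changed in Ler, 4381 upward and 3900 downward, 1378 by at least 2-fold.

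Of the 3 splicing factor lists, 2 passed the list test in Ler with the preset correlation. Of 32 Sm, LSm and U1 snRNP genes 21 rose and 1 fell (23 and 1 adjusted over the list alone; p = 1.52e-06, but adjusted p = 0.581 with an estimated correlation), with SmD1a at 0.83 (SE 0.12) and SmD3a at 0.62 (SE 0.10). Of 22 SR and hnRNP genes 12 rose and 1 fell (12 and 1 adjusted over the list alone; p = 0.00678, but adjusted p = 0.653 with an estimated correlation), with SR34A at 1.03 and SC35 at 0.46. Of 15 U2, U5 and NTC factors 4 rose and 0 fell (4 and 0 adjusted over the list alone; list test adjusted p = 0.15), PRP8B by 0.94. Of 10 genes linked to PRMT5 in earlier work 6 rose and 2 fell (6 and 2 adjusted over the list alone; p = 0.0491, but adjusted p = 0.485 with an estimated correlation), FLK (in the Col region of chromosome 3) rising by 1.54 (SE 0.07) and KRP1 by 0.92. Photosynthesis genes fell again, 21 of 29 against 4 that rose (21 and 4 adjusted over the list alone; p = 5.44e-05, but adjusted p = 0.581 with an estimated correlation), LHCB1-4 from 3720 to 1090 CPM. Of 25 glucosinolate genes 14 rose and 5 fell (14 and 6 adjusted over the list alone; p = 0.0126, but adjusted p = 0.581 with an estimated correlation), with CYP79F2 at 0.98.

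Salicylic acid and camalexin defence genes rose in Ler prmt5-5: 19 of 25 rose and 0 fell (21 and 0 adjusted over the list alone; p = 1.52e-06, but adjusted p = 0.581 with an estimated correlation). The pathogenesis-related gene PR2 rose from 15.1 to 383 CPM (log2 4.68, SE 0.89, adjusted p = 0.00365), PR5 by 4.57 (SE 0.82), the salicylic acid synthesis gene ICS1 by 0.91 (SE 0.17) and the lipase-like immune regulator SAG101 by 1.51 (SE 0.14). The 3 Ler prmt5-5 libraries differed in these genes, with PR2 at 69.6, 634 and 446 CPM and PR5 at 22.3, 248 and 172 CPM, all above the WT ranges of 8.26 to 19.4 and 2.96 to 8.47 CPM. Cold, drought and ABA genes fell, 14 of 22 against 2 that rose (15 and 2 adjusted over the list alone; p = 4.03e-05, but adjusted p = 0.396 with an estimated correlation), including COR47 at -0.86 (SE 0.11) and the cold regulator CBF3 at -1.57 (SE 0.24). Auxin response genes fell in 11 of 13 cases and rose in 1 (11 and 1 adjusted over the list alone; p = 0.000188, but adjusted p = 0.485 with an estimated correlation), with SAUR15 at -1.43 and IAA19 falling from 12.1 to 6.03 CPM, and GH3-3 rising by 1.15. Of 6 floral organ identity genes 3 fell (4 adjusted over the list alone; p = 0.0279, but adjusted p = 0.396 with an estimated correlation), SEP3 from 6.99 to 3.7 CPM and AP1 from 1.15 to 0.0733 CPM.

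The prmt5-5 effects in Col and Ler were related across genes, with Pearson's r of 0.508 and Spearman's rho of 0.555 over 22924 genes. Of 3991 genes called in both accessions, 3890 changed in the same direction and 101 in opposite directions. Independent lists would share 649.2 upward and 484.5 downward calls, against 2220 and 1670 observed. KRP1, SR34A and AT2G04050 were among the genes that rose in both accessions, as were NAC044, NEK2 and FLK of the Col region of chromosome 3. MRU1 fell in both.

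**Figure D2:**
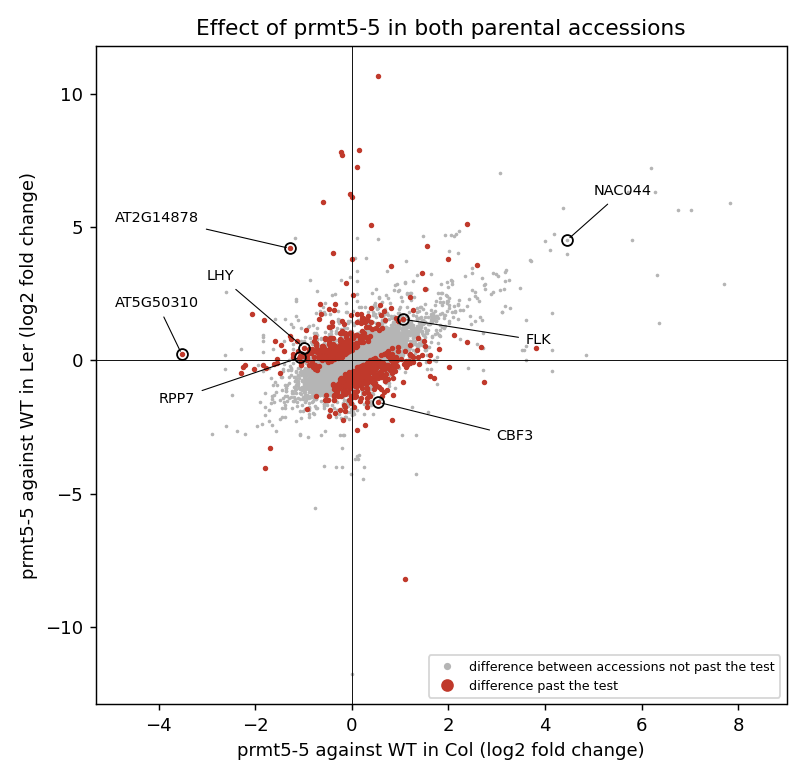
Each point is 1 of 20122 genes with a mean of at least 1 CPM across the 4 parental groups; the axes give the log2 fold change of prmt5-5 against WT in Col and in Ler. Red points are genes whose effect differed between the accessions at an adjusted p under 0.05, and AT5G50310 lies at -3.52 in Col and 0.22 in Ler.

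The accession by genotype interaction asked in which genes the effect of the mutation differed between Ler and Col. AT5G50310 differed by 3.74 on the log2 scale (SE 0.10, n = 3 per group, adjusted p = 1e-10), with 45.8 CPM in Ler WT and 53.5 CPM in Ler prmt5-5 beside its fall in Col. The downy mildew resistance gene RPP7 differed by 1.18 (SE 0.11, adjusted p = 9.39e-05), with a fall from 281 to 135 CPM in Col and values of 171 and 186 CPM in Ler. Clock genes differed in opposite ways: LHY by 1.46 (SE 0.18), CCA1 by 1.25 (SE 0.17), PRR5 by -1.19 (SE 0.16) and FKF1 by -1.29 (SE 0.19). The receptor kinase gene CRK15 had 1.18 and 0.853 CPM in Col WT and prmt5-5 and 0.685 and 10.7 CPM in Ler, a difference of 4.42 (SE 0.66, adjusted p = 0.00516), and the lectin gene AT5G03350 differed by 3.82 (SE 0.62). AT5G04120 (-2.71) and LOG2 (AT2G35990, -2.35) differed in the other direction. Of 22924 genes 741 differed, 354 upward and 387 downward.

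By list, 8 cold, drought and ABA genes of 22 had a lower effect in Ler and 1 a higher one (9 and 3 adjusted over the list alone; p = 7.04e-05, but adjusted p = 0.627 with an estimated correlation), with CBF3 at -2.12 (SE 0.32) and COR15B at -1.44 (SE 0.24). Salicylic acid and camalexin genes had a median difference of 1.78, and 1 of 25 passed the test over all genes (13 adjusted over the list alone; p = 1.15e-10, but adjusted p = 0.627 with an estimated correlation). That gene, SAG101, no longer passed in 8 of the 12 fits with 1 library left out (adjusted p up to 0.102), and Ler prmt5-5 replicate 1 lay apart in this list, with a mean log2 deviation from the mean of the 12 parental libraries of 0.385 against 1.655 and 1.38 in replicates 2 and 3. Of 27 clock genes 4 had a higher and 8 a lower effect in Ler (6 and 10 adjusted over the list alone; list test adjusted p = 0.141). Of 28 NLR genes 3 were higher and 1 lower (8 and 2 adjusted over the list alone; p = 0.00341, but adjusted p = 0.774 with an estimated correlation), with RPP4 at -0.76 (SE 0.13). Of the 3 higher ones, WRR4 no longer passed in 9 and CHS1 in 7 of the 12 fits with 1 library left out (adjusted p up to 0.0922 and 0.0741). Jasmonate genes (0 of 18 past the test; 0 adjusted over the list alone; p = 0.0277, but adjusted p = 0.774 with an estimated correlation) and root genes (1 of 21 lower; 1 higher and 1 lower adjusted over the list alone; p = 0.0192, but adjusted p = 0.627 with an estimated correlation) shifted as lists. The interaction count rested on single libraries: it was 326 without Col WT replicate 3, 347 without Col prmt5-5 replicate 3, 414 without Ler prmt5-5 replicate 3, 445 without Ler prmt5-5 replicate 2, 468 without Ler WT replicate 2 and 1751 without Ler prmt5-5 replicate 1. DESeq2 called 1597 genes.

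Differences between the accessions in WT set the background for the allelic comparisons. AOP3, an enzyme of aliphatic glucosinolate side-chain modification, had 0.215 CPM in Col and 136 CPM in Ler (log2 9.22, SE 0.23, n = 3 per group, adjusted p = 5.57e-13). The epithiospecifier gene ESP (AT1G54040) was higher in Ler by 4.98 (SE 0.17), with 56.7 and 1790 CPM. The dioxygenase gene GSL-OH was lower in Ler by -7.04 (SE 0.14) and the myrosinase gene TGG2 by -6.63 (SE 0.18), at 1350 CPM in Col and 13.6 CPM in Ler. AT2G25510 (-8.44), the retroelement SADHU1-1 (-8.01), the thionin gene AT1G66100 (-7.79) and CHS3 (-7.70) were also lower in Ler, and AT1G24370 (7.83), the phosphate transporter gene PHT1;2 (5.53) and AT5G24240 (5.17) higher. Of 22924 genes 6873 differed, 3382 higher and 3491 lower in Ler, 2248 of them by at least 2-fold. The processing notes name TAIR10 alone for alignment, and whether Ler reads aligned less well to it was not tested. Lower counts in Ler, here and between the prmt5-5 parents, may therefore come from lost reads as well as from lower expression.

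NLR immune receptor genes had mostly lower counts in Ler WT, 15 of 28 against 1 higher (15 and 2 adjusted over the list alone, list test adjusted p = 1.42e-06, but adjusted p = 0.786 with an estimated correlation). Among the lower ones were RPP2A (-4.62, SE 0.09) and RPP2B (-2.79). Lost Ler reads were not told apart from lower expression in this list. Flavonoid genes were lower in 14 of 17 cases and higher in 0 (14 and 0 adjusted over the list alone; p = 0.00013, but adjusted p = 0.828 with an estimated correlation), with chalcone synthase CHS at -0.72 (SE 0.15) and MYB111 at -1.24 (SE 0.23). Glucosinolate genes were higher in 6 and lower in 11 of 25 cases (6 and 11 adjusted over the list alone; p = 0.0378, but adjusted p = 0.828 with an estimated correlation), among the lower ones ESM1 at -3.20. Auxin response genes were higher in 7 of 13 cases and lower in 0 (9 and 0 adjusted over the list alone; p = 0.011, but adjusted p = 0.828 with an estimated correlation), with IAA1 at 0.76 and HAT2 at 0.78. Floral organ identity genes were higher in 4 of 6 cases (5 adjusted over the list alone; p = 0.0196, but adjusted p = 0.449 with an estimated correlation), SEP3 at 3.50 (SE 0.32) and AP1 at 2.56 (SE 0.44). SR and hnRNP genes were higher in 5 of 22 cases and lower in 0 (5 and 0 adjusted over the list alone; p = 0.0432, but adjusted p = 0.881 with an estimated correlation). Of 27 clock genes 11 were higher and 4 lower (11 and 4 adjusted over the list alone; list test adjusted p = 0.152), PRR7 at 1.96 (SE 0.15) and LHY at -1.16 (SE 0.13). FLC (-2.19) and MAF4 (-2.35) were lower in Ler, and SOC1 (0.74) was higher.

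Between the prmt5-5 parents, 6571 genes differed, 3272 higher and 3299 lower in Ler. AOP3 (9.43, SE 0.22), GSL-OH (-8.04, SE 0.15) and TGG2 (-6.93, SE 0.19) again differed strongly, and PCR1 was higher in Ler by 6.87 (SE 0.93). FLC was lower in Ler by -3.92 (SE 0.45, adjusted p = 1.27e-05), the NLR gene SNC1 by -2.29 (SE 0.07) and PAP1 by -1.93 (SE 0.30). Salicylic acid and camalexin genes were higher in Ler in 16 of 25 cases and lower in 0 (17 and 0 adjusted over the list alone; p = 1.22e-05, but adjusted p = 0.869 with an estimated correlation), with PNP-A at 5.37 (SE 0.65) and SAG101 at 1.36 (SE 0.14); Ler prmt5-5 replicate 1 was again lower than the other 2. Jasmonate genes were lower in 9 of 18 cases and higher in 1 (10 and 1 adjusted over the list alone; p = 0.00598, but adjusted p = 0.869 with an estimated correlation), VSP2 at -3.11. Sm, LSm and U1 snRNP genes were higher in 13 of 32 cases and lower in 1 (14 and 1 adjusted over the list alone; p = 0.000521, but adjusted p = 0.869 with an estimated correlation), with GEMIN2 at 0.62 and SmD2a at 0.45. Flavonoid genes were lower in 12 of 17 cases and higher in 0 (13 and 0 adjusted over the list alone; p = 7.57e-05, but adjusted p = 0.869 with an estimated correlation). Cold, drought and ABA genes were lower in 9 and higher in 3 of 22 cases (10 and 3 adjusted over the list alone; p = 0.0161, but adjusted p = 0.869 with an estimated correlation), KIN2 at -1.66.

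The F1 hybrids asked how the mutation acts when both genomes share a nucleus. In F1 Col x Ler, AT5G28053 rose by 4.94 (SE 0.41, n = 3 per group, adjusted p = 1.51e-05), EDA14 by 3.31 (SE 0.37), the dehydration-responsive gene RD22 by 2.94 (SE 0.24), AT3G16940 by 2.69 (SE 0.34) and NEK2, of the Col region of chromosome 3, by 2.40 (SE 0.27). MRU1 fell by 2.60 (SE 0.30) and the transporter gene UMAMIT17 by 2.05 (SE 0.22). CCA1 fell by 1.14 (SE 0.18) and LNK2 by 1.51 (SE 0.23), PRR3 rose by 1.17 (SE 0.18), and KRP1 (1.15), FLK (0.90, in the same region as NEK2), MAF1 (0.87) and MAF5 (1.91) rose. Of 28 photosynthesis genes 1 rose and 8 fell (2 and 15 adjusted over the list alone; p = 4.33e-07, but adjusted p = 0.299 with an estimated correlation), and GAPA was the one that rose, by 1.80 (SE 0.23). Of 11 floral repressors 2 rose and 0 fell (5 and 0 adjusted over the list alone; p = 0.0013, but adjusted p = 0.166 with an estimated correlation). Of 10 genes linked to PRMT5 in earlier work 2 rose and 0 fell (4 and 0 adjusted over the list alone; p = 0.00453, but adjusted p = 0.166 with an estimated correlation). Of 19 SR and hnRNP genes 3 rose and 0 fell (5 and 0 adjusted over the list alone; p = 0.0191, but adjusted p = 0.699 with an estimated correlation). Of 17301 genes 1005 changed, 672 upward and 333 downward. The count was 410, 419, 526, 582, 590 and 645 without WT replicate 2, prmt5-5 replicate 2, prmt5-5 replicate 3, prmt5-5 replicate 1, WT replicate 3 and WT replicate 1.

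In F1 Ler x Col, the bZIP factor gene TGA9 rose by 3.88 (SE 0.38, n = 3 per group, adjusted p = 1.79e-05), CHR34 by 3.76 (SE 0.50), EDA14 by 3.75 (SE 0.33), NAC044 (in the Col region of chromosome 3) by 3.83 (SE 0.67) and RD22 by 2.74 (SE 0.21). AT2G16005 fell by 3.44 (SE 0.59), MRU1 by 3.19 (SE 0.34) and AT2G05510 by 2.77 (SE 0.44). Photosynthesis genes fell in 18 of 28 cases and rose in 1 (22 and 1 adjusted over the list alone; p = 6.02e-12, but adjusted p = 0.157 with an estimated correlation), with LHCB6 at -1.14 (SE 0.14) and RBCS3B at -0.94 (SE 0.12), and GAPA rising by 1.52 (SE 0.22). Of 18 Sm, LSm and U1 snRNP genes 6 rose and 0 fell (7 and 0 adjusted over the list alone; p = 0.00107, but adjusted p = 0.548 with an estimated correlation), with SmD1a at 1.03 (SE 0.15). Of 19 SR and hnRNP genes 6 rose and 0 fell (7 and 0 adjusted over the list alone; p = 0.0016, but adjusted p = 0.548 with an estimated correlation), with SR34A at 1.18 (SE 0.21). Of 11 floral repressors 5 rose and 0 fell (7 and 0 adjusted over the list alone; p = 0.00233, but adjusted p = 0.157 with an estimated correlation), with MAF5 at 2.24 (SE 0.25). Of 10 genes linked to PRMT5 in earlier work 5 rose and 1 fell (7 and 1 adjusted over the list alone; p = 0.00212, but adjusted p = 0.157 with an estimated correlation). Of 24 glucosinolate genes 0 rose and 7 fell (1 and 8 adjusted over the list alone; p = 0.00635, but adjusted p = 0.548 with an estimated correlation), TGG2 by 1.60. Salicylic acid and camalexin genes passed the test in 0 of 22 cases in edgeR in both crosses (0 adjusted over the list alone), with a list median of 0.263 in F1 Col x Ler and of 1.613 in F1 Ler x Col (list test adjusted p = 0.502 and 0.0514), and PR2 ranged from 2.78 to 297 CPM within F1 Ler x Col prmt5-5. Of 17301 genes 2573 changed, 1370 upward and 1203 downward, and the count was 1576 without prmt5-5 replicate 3 and 1481 in a fit of the compared groups alone. The F1 crosses were not shown to differ: the difference of the prmt5-5 effect between them passed the edgeR test in 0 of 17301 genes (756 at an unadjusted p under 0.05, 12 in DESeq2), and Pearson's r between the effects was 0.691 and Spearman's rho 0.629 across genes.

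**Figure D3:**
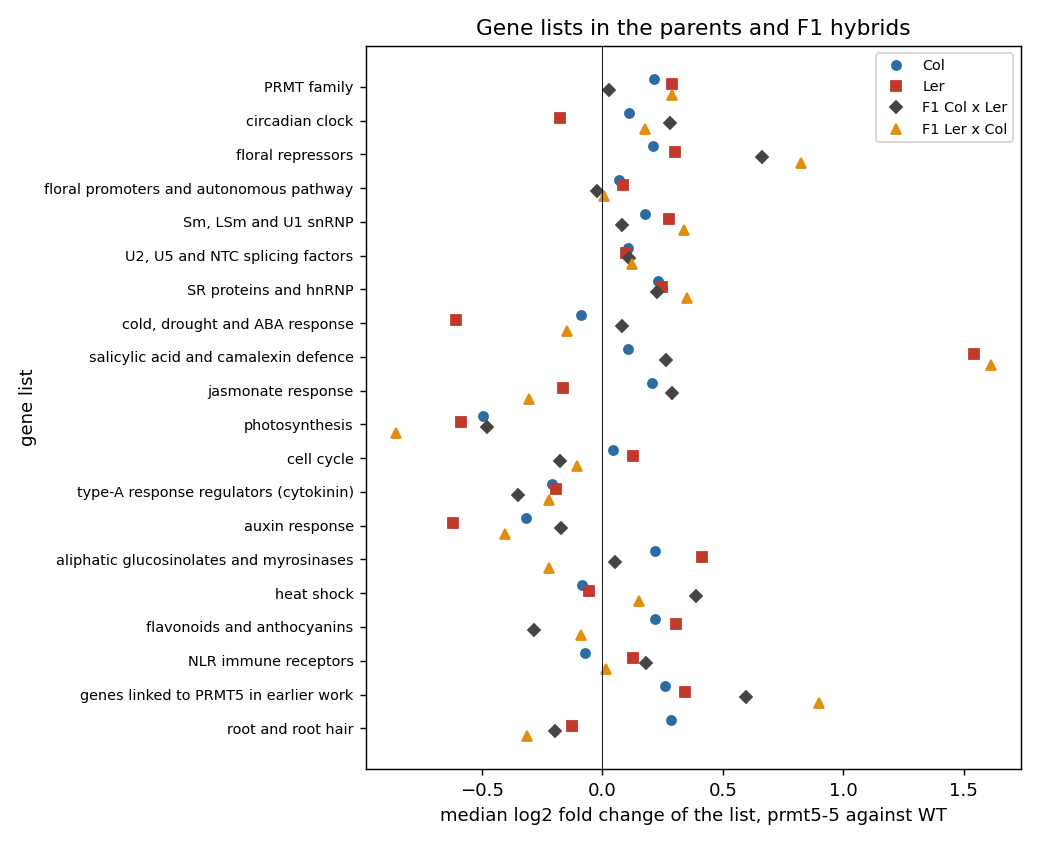
Median log2 fold change of prmt5-5 against WT of each gene list in Col, Ler and both F1 hybrids, for the lists other than seed storage and floral organ identity, which had 2 or fewer genes measured in the F1 libraries. Photosynthesis lies below 0 in all 4 backgrounds, and the salicylic acid list lies at 0.11 in Col, 1.54 in Ler, 0.263 in F1 Col x Ler and 1.613 in F1 Ler x Col.

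The F1 allele counts also located regions with a lowered Ler share in prmt5-5 F1. They are called Col segments or Col regions throughout. At PRMT5 itself Col origin follows from the crosses. For the rest of these regions it is a candidate explanation, which is weighed further below. On chromosome 4, a run of 219 informative genes between 14730215 and 16176328 (TAIR10.1) that includes PRMT5 had a Ler share under 10% in the prmt5-5 F1 of both crosses in 211 genes. Its median Ler share per library was between 0% and 0.1% in prmt5-5 F1. Among its genes, GLDP1, a subunit gene of glycine decarboxylase, had a Ler share of 50.7% in WT F1 and 0.4% in prmt5-5 F1, and the vernalization-related gene VEL1 had 47.4% and 2%. The splicing factor gene RSZ22 and the NLR gene ADR1-L1 lay in the same run. Lowered shares that varied between libraries were found on chromosome 2 from 6200001 to 6800000 (median Ler share 14.3%, 19.3%, 7.9%, 0%, 20.4% and 19.6% in the 6 prmt5-5 F1 libraries) and on chromosome 3 from 1 to 1400000 (37.7%, 22.1%, 13.2%, 49.6%, 14.3% and 31.8%). FLK, PTB1, NAC044 and NEK2 lie in the region of chromosome 3, and AT2G14878 and the receptor-like protein genes RLP18 and RLP19 in that of chromosome 2. Between WT parents, 25.9% of the genes in the chromosome 4 segment differed and 29% of those in the other 2 regions; between prmt5-5 parents these were 12.6% and 13.6%. Genes of these 3 regions are marked or named apart in the comparisons of Ler and F1 for this reason. They stayed in the list counts and list tests. Among them are RSZ22 and PTB1 of the SR protein and hnRNP list. The salicylic acid and camalexin list and the Sm, LSm and U1 snRNP list also hold members in these regions. AT2G14878 (interaction 5.48), RLP18 (3.78) and, on chromosome 4, AT4G33070 (2.77) are interaction genes in them, and 671 of the 741 interaction genes lay outside the 3 regions.

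**Figure D4:**
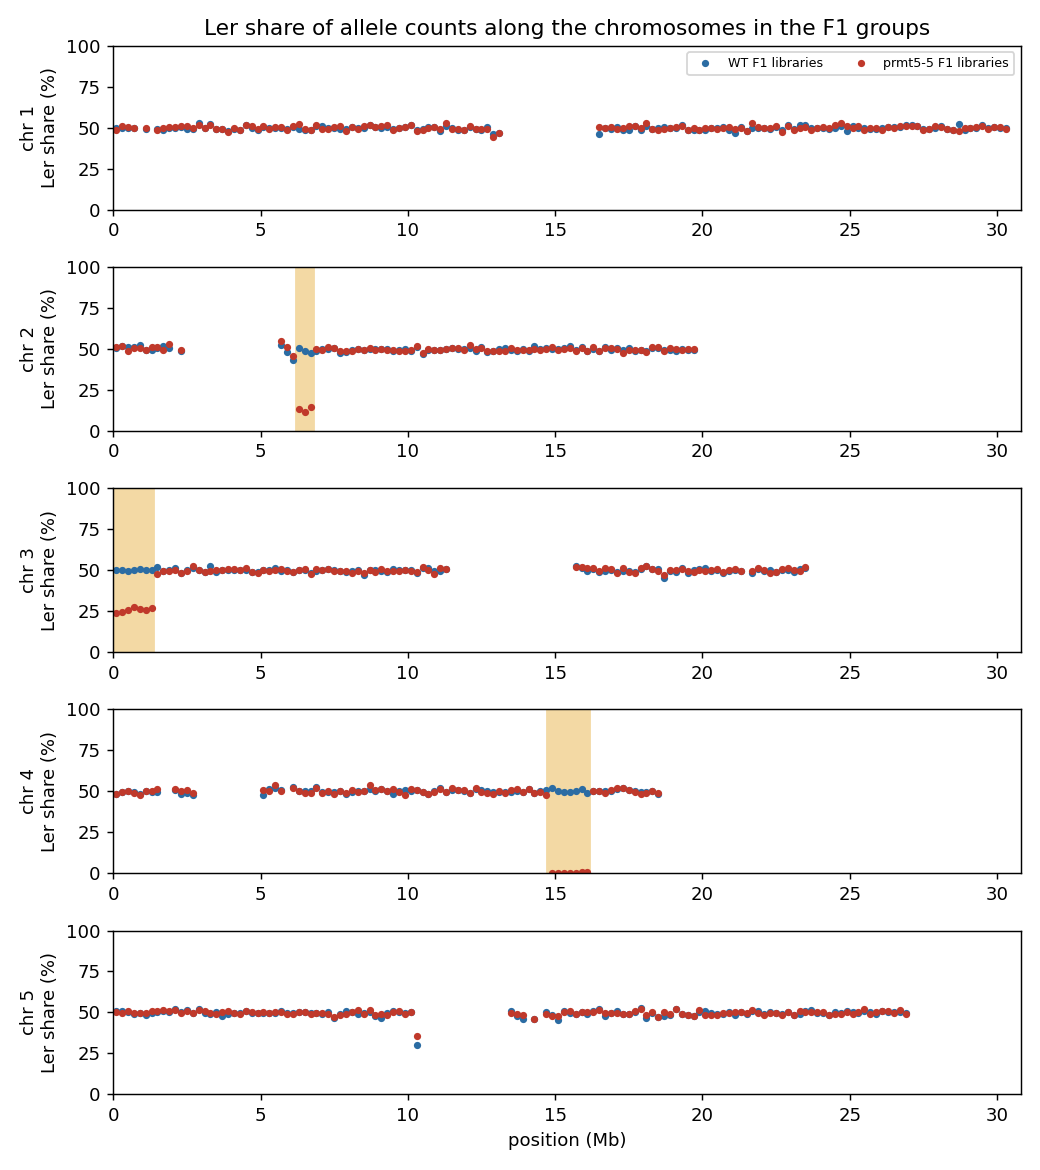
Ler share (%) of allele counts in bins along the 5 chromosomes (position in Mb), each point the median over the genes of a bin with at least 10 genes, from the pooled counts of the 6 WT or the 6 prmt5-5 F1 libraries. Shaded bands mark the regions on chromosomes 2, 3 and 4 where the prmt5-5 F1 libraries fell below WT.

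The allelic comparison in WT F1 asked which differences between the accessions persist between alleles in the same cells. The Ler allele of AOP3 exceeded the Col allele by 9.12 (SE 0.10, n = 6 libraries, adjusted p = 8.77e-38) and that of ESP by 5.44 (SE 0.05), with a Ler share of 97.7%. The cysteine desulfhydrase gene DES1 had a Ler share of 94.7% (log2 4.20, SE 0.07) and AT1G24370 a ratio of 6.44 (SE 0.06). The Ler allele was lower in TGG2 (-6.59, SE 0.13), GSL-OH (-5.79, SE 0.26) and ESM1 (-4.85, SE 0.09). In each of these genes all 6 libraries had the same sign. AT5G03880 (4.10) and the dehydrin gene AT1G54410 (-7.85) also had extreme ratios, but their parents had similar levels (216 and 233 CPM, and 770 and 931 CPM, in Col and Ler), so these ratios are uncertain. Of 15986 genes 5106 differed between alleles, 2417 with a higher Ler allele and 2689 with a higher Col allele.

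Photosynthesis alleles were higher from Ler in 5 and from Col in 14 of 28 genes (5 and 14 adjusted over the list alone), with RBCS1B at -1.96 (SE 0.02) and LHCB2-1 at -0.96 (SE 0.01). NLR alleles were higher from Ler in 7 and from Col in 8 of 26 genes (7 and 10 adjusted over the list alone), with RPP2A among the latter. Glucosinolate alleles went 7 and 10 of 24 (7 and 10 adjusted over the list alone), MAM1 at -1.66 (SE 0.04). Of 14 flavonoid genes 7 had a higher Ler allele and 0 a higher Col allele (7 and 0 adjusted over the list alone), chalcone isomerase CHI at 0.63 (SE 0.06). Single examples from other lists were the mitotic kinase gene CDKB1-2 (-2.60, SE 0.19), KIN2 (-2.16, SE 0.05), the camalexin synthesis gene PAD3 (-2.28, SE 0.18), VSP2 (-1.91), PRR7 (0.58), GRP7 (-1.31), U2AF65B (0.60), PRMT1A (0.63) and MAF1 (-0.58).

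The same comparison in prmt5-5 F1 gave large ratios outside the Col segments in AOP3 (8.60, SE 0.09), ESP (5.84, SE 0.05), AT5G20750 (6.49, SE 0.17), GSL-OH (-6.67, SE 0.27) and TGG2 (-6.36, SE 0.13), with n = 6 libraries. PRR7 had a ratio of 1.04 (SE 0.05), U2AF65B of 0.63 and CDKB1-2 of -2.59. The ribosomal protein genes AT1G70600 (9.15) and AT2G04390 (-5.49) had extreme ratios at similar parental levels and are uncertain for that reason. Of 15986 genes 5687 differed between alleles, 2484 with a higher Ler allele and 3203 with a higher Col allele. In the chromosome 4 segment 220 of 221 genes differed, all with a higher Col allele, and in the partial regions 275 of 328. In the lists, NLR genes were higher from Ler in 7 and from Col in 9 of 26 cases (8 and 10 adjusted over the list alone), and photosynthesis genes in 5 and 14 of 28 (5 and 14 adjusted over the list alone).

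The change of the allelic ratio between genotypes asked whether the alleles differed unequally between prmt5-5 and WT F1. Other DNA differences between the mutant and WT lines were not measured. An effect of the prmt5-5 mutation is therefore not separated from them here. The Ler share of AT5G50310 was 53.5% in WT F1 and 90.6% in prmt5-5 F1, a change of 3.08 on the log2 scale (SE 0.13, n = 6 libraries per genotype, adjusted p = 1.64e-18). The share of AT4G02850 went from 5.7% to 19% (1.83, SE 0.18) and that of AT5G47740 from 50.5% to 74.5% (1.51, SE 0.24). DES1 went from 94.7% to 83.9%, a change of -1.78 (SE 0.10, adjusted p = 8.53e-15). PAP1 changed by -1.15 (SE 0.17), PRR7 by 0.45 (SE 0.07), RPP7 by 0.38 (SE 0.05, adjusted p = 2.71e-06), RPP4 by -0.41 (SE 0.09), ESP by 0.40 (SE 0.09) and MAM1 by 0.31 (SE 0.05). In list terms, 2 NLR genes of 26 rose and 2 fell (2 and 2 adjusted over the list alone), 2 of 24 glucosinolate genes rose and 0 fell (3 and 0 adjusted over the list alone), and 0 of 28 photosynthesis genes rose and 4 fell (1 and 5 adjusted over the list alone), LHCB4-2 by 0.10 (SE 0.02). Of 15986 genes 651 changed, 186 toward Ler and 465 toward Col. The chromosome 4 segment held 215 of these and the partial regions 72, which left 364 genes, 186 toward Ler and 178 toward Col. With the genes of the 3 regions left out and p adjusted again, without a new fit, 296 genes passed. With the regions included, tests in F1 Col x Ler alone and in F1 Ler x Col alone gave 365 and 462 genes, against 651 in both. PAP1 did not pass the test in F1 Col x Ler alone, nor RPP4 in F1 Ler x Col alone.

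Cross direction did not change the allelic ratio past the threshold in any gene: edgeR called 0 of 15986 genes, with 692 at an unadjusted p under 0.05, and DESeq2 called 0. Organelle transcripts, which come from the seed parent, had 222 Col and 41 Ler counts over the 12 F1 libraries. Their mean Ler share was 19% (SD 14.4, n = 6) in F1 Col x Ler and 12.5% (SD 8.9, n = 6) in F1 Ler x Col (two-sided exact permutation p = 0.366). The Ler share over all 12 libraries was 52.5% for the chloroplast (19 Col and 21 Ler counts) and 9% for the mitochondrion (203 and 20), and the crosses did not differ past the threshold in either (two-sided exact permutation p = 0.603 and 0.481), with the chloroplast mean higher in F1 Col x Ler and the mitochondrial mean higher in F1 Ler x Col, so these counts did not show which accession was the seed parent.

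The parental difference minus the allelic difference in WT asked which accession differences were not matched between alleles in the same cells. PRR7 was higher in Ler by 1.96 between parents and by 0.58 between alleles, and the difference was 1.38 (SE 0.16, n = 3 per parental group and 6 F1 libraries, adjusted p = 3.02e-05). GRP7, an RNA-binding clock output gene, had a difference of 2.13 (SE 0.17, adjusted p = 4.74e-09), and RPP2A of -1.57 (SE 0.18). In AOP3, TGG2, CDKB1-2 and PRMT1A the difference was 0.11, -0.02, 0.07 and 0.03 and did not pass the test, with adjusted p of 0.913, 0.98, 0.937 and 0.943. Of 14789 genes 1917 passed this test, 942 upward and 975 downward. In F1 Col x Ler alone the count was 733 and in F1 Ler x Col alone 991, with fewer libraries in each.

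Sorted by both tests, 3645 genes had an allelic difference alone, 804 a parental minus allelic difference alone, 1113 both and 9227 neither. Of the 1113 genes, 311 had both terms in the same direction and 802 in opposite directions. Both tests use the same F1 libraries, so errors in them enter with opposite signs. With the allelic test from F1 Col x Ler and the other from F1 Ler x Col, 431 genes had both, 293 of them (68%) in opposite directions against 92.4 for independent lists, and 138 in the same direction against 93.7. With the crosses exchanged, 391 genes had both, 273 of them (69.8%) in opposite directions. Using different crosses removes only errors of shared libraries. A bias or read loss of one allele that is alike in both crosses still enters the tests with opposite signs. The excess of opposite directions therefore does not by itself show opposed effects. Parental and allelic differences were correlated across genes (Pearson's r 0.768, Spearman's rho 0.536). ESP, GSL-OH and TGG2 differed in the same direction between parents and between alleles.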

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

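The tests of read preference, mixed seedlings, kept Col segments, counting noise, position in the segments, immune gene levels and other splits were chosen only after the result was seen; the tests of a lost Ler copy, of lost reads of one allele and of unequal responses of alleles were set earlier.

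The first pattern is the low Ler share on chromosome 4 and on parts of chromosomes 2 and 3 in prmt5-5 F1 libraries, a signal in allele counts outside the comparisons between groups; the median share over the 6 libraries was 16.8% in the chromosome 2 region and 26.95% in the chromosome 3 region. Read preference for the Col allele is argued against by the WT F1 libraries, whose median share was 50% on chromosome 4 and at least 47.9% in the other regions, and mixed Col seedlings by a share of at least 49.9% outside the regions in prmt5-5 F1. Loss of the Ler copy alone is argued against by the summed allele counts of the chromosome 4 genes, which changed by 0.005 and -0.046 on the log2 scale in the 2 crosses. At PRMT5 itself Col origin follows from the crosses. For the rest of the regions, Col segments kept in the Ler mutant are a candidate explanation. Genes with a 2-fold or larger difference between WT parents were compared between prmt5-5 parents. The median fraction of the difference kept was 0.203 on chromosome 4 (29 genes, quartiles 0 and 0.406). It was 0.198 in the regions on chromosomes 2 and 3 (36 genes, quartiles -0.014 and 0.464), against 0.852 outside (2183 genes). How many Ler prmt5-5 plants carried the segments on chromosomes 2 and 3 stays open, since their shares differed between libraries.

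The second pattern is the different effect of prmt5-5 in Ler and Col, from the test of the difference between the accessions: 741 genes in all, 671 of them outside the 3 regions. Position of the genes themselves inside the 3 detected regions, as the whole cause, is argued against by the 90.6% of them that lay outside. It may account for part, since 8.3% of the genes on chromosome 4 and 9.1% of those in the other regions were called against 3% outside. Effects of the segments on genes elsewhere were not tested, so the segments stay open as a cause for the genes outside them. The search can miss Col pieces that are short or hold few informative genes. Undetected pieces therefore stay open as well. The high immune gene levels of Ler prmt5-5 replicates 2 and 3 stay open: the count fell to 445 and 414 without replicate 2 and replicate 3 and rose to 1751 without replicate 1, where these levels were lower, which goes with this explanation, but it also fell to between 326 and 638 without a Col library and was 800, 468 and 531 without Ler WT replicates 1, 2 and 3. A different response of the 2 alleles within the same cells may account for part of the pattern. Such a response to prmt5-5 is not told apart from other DNA differences between the mutant and WT lines, which were not measured. The allelic ratio in F1 moved in the direction of the parental difference in 372 of 544 genes with allele counts, or 68.4%. The 95% interval of 64.3% to 72.3% treats genes as independent, which they are not, so it is too narrow. Over all 15429 genes in both tests outside the regions, Pearson's r was 0.183. In the other direction, 288 of the 364 genes with an allelic change outside the regions (79.1%) had a parental difference of the same sign. Of 97 genes past both tests 95 had the same direction, against 6.4 for independent lists, but they were 17.5% of the interaction genes with allele counts, so trans effects and differences between the seedling samples stay open for most of them.

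The third pattern is a large allelic ratio in WT F1 in genes with near equal levels in the WT parents, found in 78 of 433 genes with at least a 4-fold ratio (18%), of 14290 genes. Counting noise is argued against by the prmt5-5 F1 libraries, where all 78 had the same sign and a median ratio of 3.099 on the log2 scale. Loss of the reads of one allele before counting stays open. The summed allele counts of these genes, relative to the parental counts, were lower than in 10000 random sets matched on parental level. The difference was -1.484 on the log2 scale (-1.242 against a median of 0.242). Its direction goes with such a loss. Its size is larger than losing every read of one allele would give where both alleles are expressed alike. Loss of one allele alone therefore does not account for the whole fall, and what else lowered the sums was not tested. An allelic difference offset in trans stays open as well, so AT5G03880, AT1G54410, AT1G70600 and AT2G04390 are uncertain.

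Further values came from the test of the difference between the accessions and are given without explanation. The effect of prmt5-5 differed between Ler and Col by 3.74 in AT5G50310, 1.18 in RPP7, 1.46 in LHY, 1.25 in CCA1, -2.12 in CBF3 and 4.42 in CRK15, on the log2 scale. The salicylic acid and camalexin list had a median difference of 1.78, and PR2 of this list had 69.6, 634 and 446 CPM in the 3 Ler prmt5-5 libraries. From the test of the difference between genotypes, the allelic ratio changed in 364 genes outside the 3 regions, by 3.08 in AT5G50310 and by -1.78 in DES1.

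Other splits of the libraries were fitted for each count. The real grouping gave more genes than every other split for the interaction (741 genes, highest other split 10, 1 of 100 splits as large). It also did so for the change of the allelic ratio (651 with the 3 regions included, highest other 17, 1 of 100). The same held for the allelic difference in WT F1 (5106, highest other 841, 1 of 32) and in prmt5-5 F1 (5687, highest other 348, 1 of 32). For the parental minus allelic difference it held as well (1917, highest other 927, 1 of 50). The other splits mixed accessions, genotypes or alleles within groups, and their real differences widen the spread and lower the counts. These splits therefore do not exclude chance. The splits do not bear on chance where the real count was 0, which every split reaches: the difference between the F1 effects (0 genes in edgeR; 756 at an unadjusted p under 0.05, 12 in DESeq2; highest other 12; 100 of 100 splits) and cross direction (0 genes in edgeR; 692 at an unadjusted p under 0.05, 0 in DESeq2; highest other 92; 100 of 100 splits). The splits with 12 and 92 genes may reflect differences between these F1 libraries, which varied in the Ler share on chromosomes 2 and 3 (0% to 49.6% in prmt5-5) and in immune gene levels; whether these made the splits was not tested. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05: the real counts and highest others were 6245 and 0 in Col, 8281 and 1 in Ler, 6873 and 0 for Ler against Col in WT, 6571 and 0 in prmt5-5, 1005 and 0 in F1 Col x Ler, and 2573 and 0 in F1 Ler x Col.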

How the results depend on the processing

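Some alternatives were chosen after seeing the data. They were the results without all 3 Col segments and the correlations with 1 library left out. For the parental minus allelic difference they were the tests of each cross alone and without 1 parental library. All alternatives of the difference between the F1 effects and the split of crosses for the gene categories were chosen then too. The other alternatives were planned. RLE factors, the filters on low counts and TMM over single allele columns moved no count of changed genes by over 1.5 times, and no scaling shifted the median of all genes by over 0.1. Of 5363 values of named genes over all alternatives, 4993 kept their direction and their side of the threshold, 369 no longer passed and 1 reversed: the allelic change of PNP-A, which was -0.116 without F1 Col x Ler WT replicate 3 and up to 0.684 without another library. Of 236 list values 192 held, and of 342 counts and summaries 298 held.

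An absolute log2 change of at least 1, a stricter threshold by construction, left 861 genes in Col, 1378 in Ler, 270 in the interaction, 2248 for Ler against Col in WT and 2183 in prmt5-5, 410 in F1 Col x Ler, 895 in F1 Ler x Col, 1366 and 1805 for the allelic difference in WT and prmt5-5, 342 for the change of the allelic ratio and 577 for the parental minus allelic difference. DESeq2 gave 1597 genes for the interaction and 12 for the difference between the F1 effects (the cause was not tested). A fit on the compared groups alone, with fewer samples, gave 1481 genes in F1 Ler x Col; for the interaction this alternative uses all 4 groups, is the fit reported, and was not run. In F1 Col x Ler alone, with fewer samples, there were 3209 genes for the allelic difference in WT, 365 for its change and 733 for the parental minus allelic difference, which was 991 in F1 Ler x Col alone. The change of the allelic ratio was 369 without the chromosome 4 segment and 296 without all 3 segments. Here the genes of the segments were left out and p adjusted again, without a new fit. With an estimated correlation, 0 gene lists passed in each of the 7 comparisons (lowest adjusted p 0.377 in Col, 0.396 in Ler, 0.627 for the interaction, 0.449 and 0.869 for Ler against Col in WT and prmt5-5, 0.166 and 0.157 in the F1). The Col to Ler correlation was 0.593 over genes with a mean of at least 1 CPM (the cause was not tested).

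With 1 library left out, the interaction gave between 326 and 1751 genes: 326 without Col WT replicate 3, 347 without Col prmt5-5 replicate 3, 414 without Ler prmt5-5 replicate 3, 445 without Ler prmt5-5 replicate 2, 468 without Ler WT replicate 2 and 1751 without Ler prmt5-5 replicate 1. F1 Col x Ler gave between 410 (without WT replicate 2) and 645 (without WT replicate 1), and F1 Ler x Col between 1576 (without prmt5-5 replicate 3) and 2394. Cross direction gave between 0 and 3, the latter without F1 Ler x Col prmt5-5 replicate 2, in edgeR (692 at an unadjusted p under 0.05 with all libraries, 0 in DESeq2). The correlation of effects lay between 0.45 (without Col prmt5-5 replicate 1) and 0.514 for Col and Ler, and between 0.464 (without F1 Col x Ler WT replicate 2) and 0.527 for Col and F1 Col x Ler. It lay between 0.52 and 0.619 for Col and F1 Ler x Col, and between 0.414 and 0.532 for Ler and F1 Col x Ler. For Ler and F1 Ler x Col it lay between 0.538 (without F1 Ler x Col prmt5-5 replicate 2) and 0.672. Between the F1 crosses it lay between 0.573 (without F1 Col x Ler prmt5-5 replicate 3) and 0.691. Why single libraries moved these values was not tested.

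Replicate numbers did not pair the libraries throughout: the deviations of same-numbered libraries correlated between -0.374 and 0.59, and no pair of groups had all 3 values over 0.1. Single same-numbered libraries did go together, such as replicate 3 of F1 Col x Ler WT and F1 Ler x Col WT (0.59) and replicate 1 of Ler WT and Ler prmt5-5 (0.474). Differently numbered ones did so too, such as F1 Col x Ler prmt5-5 replicate 3 and F1 Ler x Col prmt5-5 replicate 2 (0.537). A batch shared by some libraries is therefore not excluded. With a replicate block the counts were 6068 in Col, 8116 in Ler, 788 for the interaction, 6846 and 6390 for Ler against Col in WT and prmt5-5, 863 and 2512 in the F1, 692 for the change of the allelic ratio and 0 for the difference between the F1 effects. In simulated data, changes of 1.5-fold, 2-fold and 4-fold were recovered in 52.2%, 70.1% and 97% of genes in Col, in 25.4%, 52.2% and 87.9% for the interaction, in 3%, 38.8% and 83.3% in F1 Col x Ler and in 35.8%, 71.6% and 89.4% for the change of the allelic ratio. The shares were 4.5%, 37.3% and 77.3% in F1 Ler x Col and 41.8%, 58.2% and 93.9% for cross direction. The difference between the F1 effects was not simulated. False calls were between 2.2% (the change of the allelic ratio) and 9.2% (Ler) of all calls, and were over 5% as well for the interaction (7.6%), Ler against Col in WT (6.5%) and prmt5-5 (8%), F1 Ler x Col (7.1%) and the allelic difference in WT (7.5%) and prmt5-5 (5.3%). Each simulation was run a single time and changed only 67, 67 and 66 genes by 1.5-fold, 2-fold and 4-fold. Its genes varied independently, unlike those of real libraries, so these shares do not carry over directly to the real tests.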

Other observations

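The counts of genes found in 1 accession alone and the levels per library in this part were chosen only after the result was seen; the list counts were planned. Members of further lists passed the test in Ler prmt5-5, but the lists did not pass the list test (lowest adjusted p 0.0571, in the PRMT family, with the preset correlation). Of 27 circadian clock genes 3 rose and 10 fell (3 and 11 adjusted over the list alone), with PRR9 at 0.62 (SE 0.14) and PRR5 at -0.57 (SE 0.11). Of 18 jasmonate genes 2 rose and 5 fell (2 and 5 adjusted over the list alone), with the storage protein gene VSP1 at -1.10 (SE 0.19). Of 28 NLR genes 6 rose and 1 fell (6 and 1 adjusted over the list alone), WRR4 at 1.73 (SE 0.26) and SNC1 at -0.40 (SE 0.07). Of 17 flavonoid genes 6 rose and 2 fell (6 and 2 adjusted over the list alone), of 9 PRMT family genes 5 rose and 1 fell (5 and 1 adjusted over the list alone), with PRMT3 at 0.68 (SE 0.11), and of 12 floral repressors 4 rose and 0 fell (4 and 1 adjusted over the list alone). SOC1 fell by 0.80 (SE 0.10) in Ler as it fell in Col.

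Immune gene levels separated libraries within groups of F1 hybrids. PR2 had 17.5, 16.2 and 211 CPM in the 3 F1 Col x Ler prmt5-5 libraries and 2.78, 297 and 28.1 CPM in F1 Ler x Col prmt5-5, against 1.06, 3.63 and 33.1 CPM and 1.69, 1.52 and 9.75 CPM in the WT libraries of the same crosses. PR5 went with it, with 33.7, 25.5 and 197 CPM and 27, 184 and 98.5 CPM in the same prmt5-5 libraries.

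Of the genes with a mean of at least 1 CPM in one accession, 16 had 0 counts in all 6 Ler libraries and 13 had 0 counts in all 6 Col libraries. Their median levels in the other accession were 1.94 and 2.25 CPM. Whether reads of Ler were lost in alignment to TAIR10 in the genes with 0 counts in Ler was not tested.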
